A study of Rattus norvegicus with 3 samples.

How the data were processed

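RNA of 3 rat samples was measured on 1 Affymetrix array each. The labels give 1 time label per array (0.0 h, 0.1 h and 1.0 h) and total RNA as the molecule; the treatment, the number of animals and the tissue of each single sample are not given in the sources used here. The deposited values are 1 linear intensity per probe set. The probe set summary method, the background correction and the software are not given in the sources used here. From the deposited intensity values themselves, the mean of each array without its highest and lowest 2% of values was 2503.7, 2503.9 and 2503.7, so the arrays had been brought to a common mean before deposit.

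Of 8799 probe sets, 59 were controls and were left out of all counts. The other 8740 were named through the platform's probe annotation: 7006 had 1 gene symbol, 308 had several and 1426 were not named there. Of the 7006, 6985 were matched by gene ID to a RefSeq gene table of the assembly GRCr8, which changed 0 symbols and was used for names and gene lengths, with no coordinates. Probe sets with several symbols were not used for named genes. There were 4736 genes, of which 1565 had 2 or more probe sets, and a gene was represented by its probe set with the highest mean log2 value over the 3 arrays.

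Intensities were taken to log2 and scaled to the array median, and the floor was set at the 40th percentile of all values of the 3 arrays, an intensity of 262.9. The arrays were then shifted so that the medians over probe sets above the floor on all 3 arrays were equal, by 0.008, 0.042 and -0.05 for 0.0 h, 0.1 h and 1.0 h. Differences between 2 arrays were taken only where both were above the floor, and a probe set was counted when the arrays were at least 2-fold apart. With 1 array per label there were no p-values and no standard errors across arrays. The SD of the log2 differences was taken from the median absolute deviation across probe sets and describes these arrays. The floor left 5140, 5290 and 5319 probe sets above it, and the number of arrays limits the precision.

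A list of genes was described by the median log2 difference of its measured members, the number at least 2-fold apart in each direction, and the percentile of its median among 10000 random lists of the same size matched on mean level in 20 bins. A shift common to all probe sets of an array moves the median but hardly the percentile, which is relative to other genes. The 25 lists, the 3 comparisons, the floor, the rule for named genes and the alternatives were fixed before the data were examined. They cover immediate early, pinealocyte, phototransduction, chromaffin, adrenal cortex, circadian clock, cyclic AMP, heat shock, glucocorticoid, inflammatory, ribosomal, oxidative phosphorylation, proteasome, cell cycle and housekeeping genes. Cell type markers were those of leukocytes, endothelium, fibroblasts and smooth muscle, astrocytes, oligodendrocytes and Schwann cells, central neurons, choroid plexus, erythroid cells, skeletal muscle and adipocytes. Another 3 lists (splicing and RNA processing; MHC class I, antigen processing and interferon; vacuolar ATPase) the reading of each gene from its second-brightest probe set and the scaling to spike-in probe sets were added after the values had been seen.

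Named genes were, for each comparison, the 12 highest and 12 lowest genes with a single symbol, above the floor on both arrays and above the 60th percentile on the brighter. To these came list members at least 2-fold apart, up to 4 per direction, or the 2 brightest members where fewer than 2 were, and a fixed set of melatonin, catecholamine and steroid genes. The rule also asked for genes at the floor on 1 array and above the 75th percentile on the other, and it gave none. Not every gene given by the rule is printed below. Where the measured probe sets of a printed gene disagreed in direction, the text says so.

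The alternatives were the values as deposited, quantile normalisation, cyclic loess normalisation (limma 3.58.1 in R 4.3.3), the floor at the 20th or the 60th percentile, the mean of all probe sets of a gene, the added second-brightest probe set, and for list medians and counts an added shift of each array that made the mean log2 value of the 9 spike-in probe sets equal, with the probe sets above the floor kept. The mean of all probe sets of a gene took in its probe sets below the floor. For the second-brightest reading, probe sets with _g_at in their names were left out before ranking. Scaling as an explanation of a list's median was first planned as a test of its percentile. That test was dropped because a common shift hardly moves a percentile. Medians under the other scalings were instead set against 2 bootstrap standard errors of the median under the main scaling. The bootstrap drew list members, which are not independent replicates. Only quantile and cyclic loess normalisation, which move genes differently, counted in this test, since the deposited scaling and the spike-in scaling are 1 factor per array and move all genes alike. The overlap of the comparisons that share the 0.0 h array was set against 100 simulated sets of unchanged arrays. The procedure was tested on simulated data with 200 changed probe sets per comparison. For 0.1 h against 0.0 h it recovered 53.0% of 2-fold and 95.0% of 4-fold changes, for 1.0 h against 0.0 h 49.5% and 98.5%, and for 1.0 h against 0.1 h 49.0% and 96.5%. Its noise was drawn with the spread of the observed differences, so real differences widen it, and unchanged probe sets also passed the 2-fold threshold: 342 and 405, 167 and 203, and 401 and 446 in the same order. A shift of up to 0.058 in the median log2 difference was left by the scaling in these simulations; the bound the test applied to this shift was widened to 0.1 after the shift had been seen. Tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.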

Results

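Transcript levels were measured on 3 rat expression arrays, 1 for each of the time labels 0.0 h, 0.1 h and 1.0 h of a time course. The labels give pineal gland and adrenal medulla together as the source of every sample and do not name the treatment. Whether 0.1 h is a true time could not be settled from the labels, and the sample numbers in the titles do not follow the order of the time labels. The pineal gland makes melatonin, and the adrenal medulla makes catecholamines. Each array held 8799 probe sets, and the deposited values were linear intensities with medians of 401.5, 430.2 and 457.6 on the 0.0 h, 0.1 h and 1.0 h arrays. After scaling, 58.8%, 60.5% and 60.9% of the probe sets other than controls lay above an intensity floor of 262.9. There was 1 array per time label, so no difference below has a replicate check, no test of the conditions was possible, and the number of arrays limits the precision of every value.

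A fixed set of melatonin, catecholamine and steroid genes was read against the floor on each array. Tph1, the tryptophan hydroxylase of the pineal gland, had intensities of 22074, 16982 and 22618 at 0.0 h, 0.1 h and 1.0 h. Asmt, which carries out the last step of melatonin synthesis, had 5746, 13864 and 9167. Aanat, the enzyme before it, was below the floor at 0.0 h with 253.0 and above it at 0.1 h and 1.0 h with 400.8 and 506.0. Th, the first enzyme of catecholamine synthesis, was below the floor on all 3 arrays with 136.8, 202.3 and 183.0, as was Dbh with 90.8, 56.1 and 101.6. Pnmt, which makes adrenaline, was above the floor with 610.7, 657.5 and 514.2. The steroidogenic genes Star and Cyp11a1 were below the floor on all 3 arrays. Per1, Chga and Cyp11b1 had no probe set named for them alone.

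The comparison of 0.1 h with 0.0 h asked which transcripts differed between the arrays labelled 0.1 h and 0.0 h. Immediate early genes, which neurons and other cells switch on within minutes of a stimulus, were higher on the 0.1 h array: 5 of 26 measured members were at least 2-fold higher, and none was 2-fold lower. Nr4a1 was 4.28-fold higher, the cyclooxygenase gene Ptgs2 3.39-fold, the transcription factor gene Egr1 3.28-fold and Fos 2.22-fold. The other measured probe sets of Fos had log2 differences of 0.80 and 0.38. Inflammatory and acute phase genes were higher as well, with 3 of 19 at least 2-fold higher, among them the chemokine genes Cxcl2 at 3.17-fold and Ccl20 at 2.07-fold and the cytokine gene Il6 at 2.06-fold. Oxidative phosphorylation genes had 12 of 52 members at least 2-fold higher and 2 at least 2-fold lower. This list was picked by gene name. It holds genes of the mitochondrial respiratory chain and of ATP synthase, and also assembly factor genes such as Ndufaf3. Its complex I subunit genes Ndufb6, Ndufb9 and Ndufb5 were 5.13-fold, 4.64-fold and 3.85-fold higher. Cox7b, with a dim 371.0 at 0.0 h, was 3.38-fold higher, while Cox4i2 and Sdha were 2.26-fold and 2.11-fold lower.

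The median log2 difference of the immediate early list between 0.1 h and 0.0 h was 0.53, at percentile 100 among 10000 random lists of the same size and like level. The inflammatory list had a median of 0.52 at percentile 99.85, and the oxidative phosphorylation list 0.56 at percentile 100. Heat shock and unfolded protein genes had a median of 0.28 at percentile 99.48, with 2 of 22 at least 2-fold higher: the chaperone genes Hsph1 at 2.59-fold and Canx at 2.04-fold. Cytosolic ribosomal protein genes had a median of 0.19 at percentile 98.7, with 4 of 39 at least 2-fold higher, including Rpl17 at 2.55-fold and Rplp0 at 2.22-fold. Adipocyte markers had a median of 0.43 at percentile 98.15 over 8 measured genes, with Cfd 2.19-fold and Lep 2.17-fold higher and Cidea 2.67-fold lower. The 3' to 5' ratio of the beta-actin control, which grows as RNA breaks down, was 10.4 at 0.0 h and 17.8 at 0.1 h, and that of GAPDH was 15.3 and 18.6. On all 3 arrays both controls were at least 10.4-fold brighter at the 3' end, which limits every comparison. The 9 spike-in probe sets, which are hybridisation controls, had a median log2 difference of 0.23 and a mean of 0.28 between these arrays. With the arrays shifted to make that mean 0, an alternative chosen after the data were seen, the immediate early, inflammatory, oxidative phosphorylation and ribosomal medians were 0.25, 0.24, 0.28 and -0.09, the heat shock median 0 and the adipocyte median 0.15. The inflammatory median was 0.33 with the floor at the 20th percentile, and the ribosomal median 0.12 with quantile normalisation. When each gene was read from its second-brightest probe set, the immediate early median was 0.16, at percentile 44.8 over 6 genes, the inflammatory median 0.57, at percentile 96.92 over 6 genes, and the oxidative phosphorylation median 0.75, at percentile 99.84 over 12 genes. On second-brightest probe sets the heat shock median was 0.33 at percentile 80.23, the ribosomal median 0.30 at percentile 79.91 and the adipocyte median -0.24 at percentile 8.68. With quantile normalisation and with probe sets averaged the adipocyte median lay at percentiles of 97.3 and 96.6.

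Among single genes, Jtb stood farthest apart, with 2385, 61102 and 3468 on the 3 arrays, a 25.62-fold higher level at 0.1 h than at 0.0 h from 1 probe set. The mitochondrially encoded COX3 was 4.77-fold higher, the chromatin protein gene Hmga1 4.44-fold, Vdac1, which encodes a channel of the outer mitochondrial membrane, 4.10-fold, and Mpc1, a subunit of the mitochondrial pyruvate carrier, 3.90-fold. Map2k1, a kinase of the ERK pathway, was 3.92-fold higher on its brightest probe set. Its other measured probe set was nearly level, with a log2 difference of -0.03. Glod4 and Akap11 were 4.49-fold and 3.81-fold higher. The lowest genes relative to 0.0 h were Arrdc4 at 4.60-fold, Tnrc6b at 4.52-fold and the splicing regulator gene Rbm39 at 4.24-fold lower, followed by Ubac2, Slco2a1 and Tbc1d2b. Pde4b, a cyclic AMP phosphodiesterase gene, was 3.52-fold lower on its brightest probe set, but its log2 difference was 0.11 when all its probe sets were averaged. Only 1 of its 4 probe sets, the brightest, was above the floor on both arrays. Srpk2 and Cpsf7, which act in RNA processing, were 3.51-fold and 3.37-fold lower, and Lhb, Cipc and LOC102546572 were also among the 12 lowest. Averaging probe sets brought Hsph1 and Slco2a1 under 2-fold, with log2 differences of 0.84 and -0.80, and gave 1.58 for Ndufb6, 1.34 for Ndufb5, 1.27 for Map2k1 and -1.03 for Srpk2. Fos and Lep also fell under 2-fold when averaged. The other probe sets of Hsph1, Slco2a1, Lep and Ndufb5 were not above the floor on both arrays. In all, 294 of 4743 probe sets above the floor on both arrays were at least 2-fold higher at 0.1 h and 206 at least 2-fold lower, with an SD of the log2 differences of 0.53; with the spike-in probe sets made equal the counts were 134 and 462.

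The comparison of 1.0 h with 0.0 h asked which transcripts differed at the last time label. Immediate early genes were again higher than at 0.0 h, with 6 of 25 measured members at least 2-fold higher and none 2-fold lower. Klf4 was 3.68-fold higher, Nr4a1 3.30-fold, Egr1 2.54-fold, Ptgs2 2.38-fold and Fos 2.20-fold. The 3 measured Egr1 probe sets had log2 differences of 1.34, 1.29 and -0.09, so the 1 that was lower was nearly level. Inflammatory genes had 4 of 21 at least 2-fold higher: Cxcl2 at 3.00-fold, Il6 at 2.41-fold, the interferon regulatory factor gene Irf7 at 2.11-fold and the chemokine gene Ccl2 at 2.01-fold. Ly6c, an endothelial and leukocyte surface antigen, was the highest gene at 5.27-fold, and Coro1a, an actin-binding protein gene of leukocytes, and Tap1, a transporter of antigen peptides, were 4.10-fold and 3.26-fold higher.

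The immediate early median between 1.0 h and 0.0 h was 0.29 at percentile 99.46, and the inflammatory median 0.31 at percentile 99.36. On second-brightest probe sets these medians were 0.03 at percentile 45.29 and 0.22 at percentile 86.76, over 6 genes each, and with the floor at the 60th percentile the inflammatory median was 0.24 at percentile 94.92; averaging probe sets gave 0.75 for it. Macrophage and leukocyte markers had a median of 0.33 at percentile 97.55 over 14 genes, although Spp1 and Fcer1a were 2.78-fold and 2.42-fold lower; averaging probe sets gave 0.17 at percentile 83.65, and quantile and cyclic loess normalisation gave percentiles of 97.19 and 97.38. Endothelial markers had a median of 0.65 at percentile 98.38 over 5 genes, with Flt1 1.57-fold higher and Kdr 1.17-fold lower; averaging probe sets gave 0.26 at percentile 81.43, and the floor at the 20th percentile gave 0.37 at percentile 89.35. Circadian clock genes had a median of -0.33 at percentile 2.27, and Bmal1 was 2.13-fold lower on its brightest probe set while its other probe set was higher. With the floor at the 20th or 60th percentile, or with probe sets averaged, the clock median lay at percentiles of 4.01, 3.36 and 3.16. Oxidative phosphorylation genes had a median of 0.05 at percentile 94.94, and of -0.04 with probe sets averaged. Of 52, 5 were at least 2-fold higher, led by Ndufb6 at 4.32-fold and Cox7b at 4.06-fold. The 1 at least 2-fold lower was the assembly factor gene Ndufaf3. Ribosomal protein genes had a median of -0.09, and of 0.13 on second-brightest probe sets. The beta-actin 3' to 5' ratio was 44.4 at 1.0 h against 10.4 at 0.0 h, and that of GAPDH 14.1 against 15.3. The spike-in probe sets had a median log2 difference of -0.19 and a mean of -0.20; with that mean made 0 the immediate early, inflammatory, oxidative phosphorylation and ribosomal medians were 0.49, 0.51, 0.25 and 0.11, and the clock, leukocyte and endothelial medians -0.13, 0.53 and 0.85.

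The genes lowest at 1.0 h relative to 0.0 h were Elovl5, which elongates fatty acids, at 5.66-fold, and Nedd4, a ubiquitin ligase gene, at 5.49-fold lower. Atp6v1a, a subunit of the vacuolar proton pump, was 4.76-fold lower on its brightest probe set, but 2 of its 3 probe sets were higher. Tmem64 was 4.44-fold and the peroxisomal transporter gene Abcd3 4.43-fold lower, followed by Mtch2, Tnfsf13, Pafah1b1 and Cul2 at 3.82-fold, 3.80-fold, 3.68-fold and 3.60-fold. Sardh, Mboat7 and Tc2n completed the 12 lowest genes. Averaging probe sets brought Il6, Mtch2, Fcer1a, Atp6v1a and Bmal1 under 2-fold, with log2 differences of 0.82, -0.82, -0.71, -0.55 and -0.22, and gave 1.26 for Ndufb6, -1.29 for Abcd3, -1.26 for Pafah1b1 and -1.15 for Tnfsf13. For Il6, Fcer1a, Pafah1b1 and Tnfsf13 the mean took in a probe set that was not above the floor on both arrays. Prr13, Nrbp1, Glod4 and Fen1 completed the 12 highest genes at 3.59-fold, 3.37-fold, 3.06-fold and 2.94-fold. At least 2-fold differences were counted for 138 probe sets higher and 123 lower of 4775, with an SD of the log2 differences of 0.44; with the spike-in probe sets made equal the counts were 261 and 63.

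Both comparisons with 0.0 h use the same 0.0 h array, so its own error enters both. Of 4576 probe sets above the floor on all 3 arrays, 64 were at least 2-fold higher at 0.1 h and at 1.0 h, against 8.1 for independent lists of 286 and 129. In 100 simulations of unchanged arrays against a shared 0.0 h array the mean was 32.5 and the maximum 48. For lower probe sets the overlap was 16, against 5.3 for independent lists of 203 and 120 and a simulated mean of 33.1. The log2 differences of the 2 comparisons had a correlation across probe sets of 0.43 and a covariance of 0.135, against 0.50 and 0.144 in the simulation. The simulation gave the 3 arrays the same spread. The observed SDs of the log2 differences were 0.53 and 0.44 in the comparisons with 0.0 h and 0.56 between the later arrays. A less noisy 0.0 h array would lower the simulated overlap, so the counts cannot be judged against it. Part of any excess may come from the shared array, which this simulation does not split off.

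**Figure D1:**
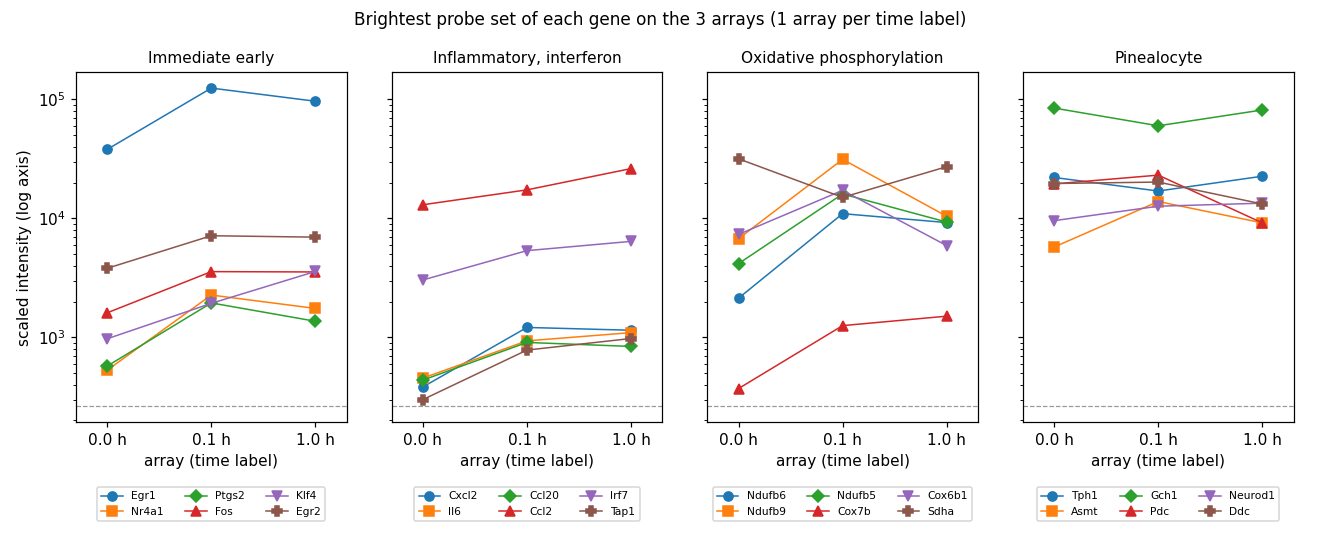
Scaled intensity on a log axis of the brightest probe set of 6 genes in each of 4 groups, by time label; each point is 1 array, lines join the arrays, and the dashed line is the floor of 262.9. Egr1 had 38024 at 0.0 h, 124584 at 0.1 h and 96557 at 1.0 h, and Ndufb9 had 6752, 31350 and 10421.

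The comparison of 1.0 h with 0.1 h asked what differed between the later arrays. Oxidative phosphorylation genes were lower at 1.0 h, with 9 of 54 measured members at least 2-fold lower and 1 at least 2-fold higher. Ndufb9 was 3.01-fold, Cox6b1 2.91-fold, Ndufb2 2.59-fold and Ndufa8 2.48-fold lower, and Cox4i2 was 2.40-fold higher. Ribosomal protein genes were lower as well, with none of 38 at least 2-fold apart, Rpl23 1.22-fold lower and Rpl3 1.36-fold lower on its brightest probe set and higher on its other one. Immediate early and inflammatory genes differed little as groups between 0.1 h and 1.0 h, with Ier3 2.37-fold lower and Fos 1.01-fold lower on its brightest probe set and higher on its other 2.

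The oxidative phosphorylation median between 1.0 h and 0.1 h was -0.37 at percentile 0.01, and the ribosomal median -0.34 at percentile 0.59. On second-brightest probe sets these were -0.65 at percentile 0.81 over 14 genes and -0.01 at percentile 66.55 over 7 genes. Quantile normalisation gave -0.21 for the oxidative phosphorylation list. The immediate early and inflammatory medians were both -0.05, at percentiles 27.63 and 37.57, and both 0.04 as deposited. Phosducin, Pdc, a protein of photoreceptors and pinealocytes, was 2.52-fold lower at 1.0 h. Several genes that were low at 0.1 h alone led the higher genes: Rbm39 at 5.64-fold, Tnrc6b at 4.70-fold, the integrin gene Itga1 at 4.21-fold, Slco2a1 at 4.04-fold, Ubac2 at 3.80-fold, Tbc1d2b at 3.71-fold, Arrdc4 at 3.61-fold and Cpsf7 at 3.50-fold. The measured probe sets of Slco2a1 disagreed in direction, with a mean log2 difference of 0.97, and averaging gave 1.21 for Cpsf7. Jtb was 17.62-fold lower at 1.0 h, Nedd4 5.42-fold, the quinone reductase gene Nqo1 5.17-fold, Elovl5 5.09-fold and COX3 3.60-fold. Of 4833 probe sets, 187 were at least 2-fold higher and 265 at least 2-fold lower, with an SD of the log2 differences of 0.56; on the values as deposited the counts were 260 and 211, and with the spike-in probe sets made equal 799 and 60. The beta-actin 3' to 5' ratio was 44.4 at 1.0 h against 17.8 at 0.1 h, and that of GAPDH 14.1 against 18.6. The spike-in probe sets had a median log2 difference of -0.61 and a mean of -0.47. With that mean made 0 the oxidative phosphorylation and ribosomal medians were 0.10 and 0.13 and the immediate early and inflammatory medians both 0.42; this shift is the same for every gene and does not change a list's place among other genes.

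The 0.1 h array stood apart from both others on more probe sets than either of them did: it was at least 2-fold higher than both on 92 and lower than both on 97. The 0.0 h array was higher than both on 16 and lower on 64, and the 1.0 h array was higher than both on 12 and lower on 62. On the values as deposited the 0.1 h counts were 72 and 121 and the 1.0 h counts 22 and 55. With the spike-in probe sets made equal the counts higher and lower than both others were 10 and 61 for the 0.0 h array, 21 and 334 for 0.1 h and 77 and 19 for 1.0 h. In simulated arrays whose noise had the spread of the observed differences, unchanged probe sets at least 2-fold apart numbered 342 and 405 in 2 simulations of 0.1 h against 0.0 h, 167 and 203 of 1.0 h against 0.0 h, and 401 and 446 of 1.0 h against 0.1 h. That spread includes any real differences, so these numbers do not show what share of the 2-fold counts arose without change. Across 4576 probe sets, which are not independent replicates, the Pearson correlation of log2 values was 0.953 for 0.1 h with 0.0 h, 0.969 for 1.0 h with 0.0 h and 0.954 for 1.0 h with 0.1 h, and the Spearman correlation 0.941, 0.959 and 0.941.

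Over the 25 gene lists and 3 comparisons, 13 of 75 medians lay outside the central 95% range of random lists, where 3.75 would by chance if the medians were independent. Of these 13, 10 were on the higher side. The other 62 medians lay inside it, between -0.41 and 0.48, and 42 of them changed sign with quantile or cyclic loess normalisation, another floor, probe sets averaged or the second-brightest probe sets, so no direction is given for these. The other 20 kept their sign under those of the alternatives that were run on them, though a shift common to all genes, as with the spike-in probe sets, turned some of them. The second-brightest probe sets in particular gave no median for many lists. Since the 20 medians lie inside the random range, their sign does not set them apart from random lists. For 0.1 h against 0.0 h they were skeletal muscle markers at 0.40, proteasome genes at 0.16, oligodendrocyte markers at 0.14, pinealocyte genes at 0.04 and clock genes at -0.07. For 1.0 h against 0.0 h they were adrenal cortex genes and erythroid markers at 0.23, adipocyte markers at 0.19, proteasome genes at 0.13, housekeeping genes at -0.09 and phototransduction genes at -0.23. For 1.0 h against 0.1 h they were endothelial markers at 0.48, erythroid markers at 0.27, leukocyte markers at 0.02, fibroblast markers at 0.01, choroid plexus markers at -0.07, clock genes at -0.09, heat shock genes at -0.18, oligodendrocyte markers at -0.28 and phototransduction genes at -0.29. Among single genes of these lists, Asmt was 2.41-fold and Mat2a, which makes the methyl donor of melatonin synthesis, 2.16-fold higher at 0.1 h than at 0.0 h, and the neuropeptide gene Npy was 2.18-fold higher at 1.0 h than at 0.1 h.

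**Figure D2:**
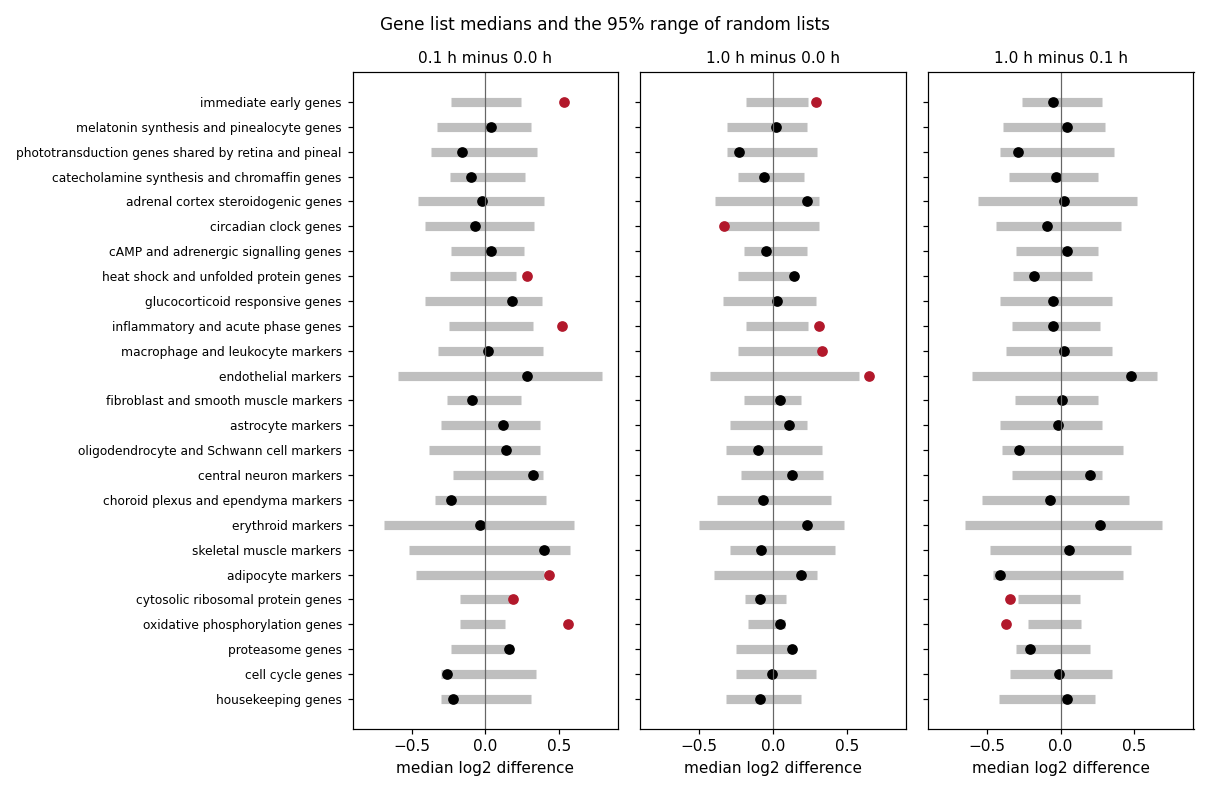
Median log2 difference of 25 gene lists in 3 comparisons; points are list medians, grey bars the central 95% range of 10000 random lists of like level, and red points lie outside that range. The oxidative phosphorylation list lies at 0.56 for 0.1 h minus 0.0 h and at -0.37 for 1.0 h minus 0.1 h.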

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

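The second-brightest probe sets, the scaling to spike-in probe sets and the 3 added lists were chosen after seeing the data; all other alternatives were planned. No paired analysis was possible because each time label had 1 array. The 15 correlations between arrays moved little, while 36 of 72 counts of probe sets at least 2-fold apart moved by over 1.5 times. Dim probe sets near the floor limit these counts: with the floor at the 20th and the 60th percentile, the higher counts were 532 and 172 for 0.1 h against 0.0 h, 354 and 64 for 1.0 h against 0.0 h, and 437 and 103 for 1.0 h against 0.1 h. The lower counts were 483 and 131, 367 and 64, and 531 and 166. For the 0.0 h array against both others they were 85 and 6 higher and 169 and 33 lower, for the 0.1 h array 173 and 56 higher and 207 and 58 lower, and for the 1.0 h array 72 and 4 higher and 158 and 38 lower. How much of these moves comes from the number of probe sets each floor admits was not tested. As deposited, 22 were higher on the 1.0 h array, and the cause was not tested.

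On second-brightest probe sets the immediate early median was 0.16 for 0.1 h and 0.03 for 1.0 h against 0.0 h, the inflammatory median -0.30 for 1.0 h against 0.1 h, the ribosomal medians 0.30, 0.13 and -0.01 in the 3 comparisons, the oxidative phosphorylation medians 0.75 and -0.65 in the comparisons with 0.1 h, and the adipocyte median at 0.1 h against 0.0 h reversed to -0.24; these lists have fewer genes with a second probe set. With the floor at the 20th percentile the inflammatory medians were 0.33 for 0.1 h against 0.0 h and 0.12 for 1.0 h against 0.1 h, and the ribosomal median at 1.0 h against 0.0 h was -0.17. Averaging probe sets gave 0.75 for the inflammatory list at 1.0 h against 0.0 h and reversed Pde4b, at 0.11 and -0.28. Of the 4 Pde4b probe sets averaged, only 1 was above the floor on both arrays. Quantile normalisation gave ribosomal medians of 0.12, -0.03 and -0.23 and an oxidative phosphorylation median of -0.21 at 1.0 h against 0.1 h; cyclic loess gave ribosomal medians of -0.02 at 1.0 h against 0.0 h and -0.25 at 1.0 h against 0.1 h, and the values as deposited -0.25 there. Quantile normalisation also placed the oxidative phosphorylation median at 1.0 h against 0.0 h, 0.15, at percentile 98.74. The cause of these moves was not tested.

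With the spike-in probe sets made equal, every probe set of a comparison shifts by the same amount. The counts higher and lower became 134 and 462 for 0.1 h against 0.0 h, 261 and 63 for 1.0 h against 0.0 h, and 799 and 60 for 1.0 h against 0.1 h. Higher than both others were 10, 21 and 77 on the 0.0 h, 0.1 h and 1.0 h arrays, and lower than both 334 on the 0.1 h and 19 on the 1.0 h array. The immediate early medians became 0.25, 0.49 and 0.42 for 0.1 h against 0.0 h, 1.0 h against 0.0 h and 1.0 h against 0.1 h, and the inflammatory medians 0.24 and 0.42 in the comparisons with 0.1 h. The ribosomal medians became -0.09, 0.11 and 0.13, reversed in the first and the last, and the oxidative phosphorylation medians 0.28, 0.25 and 0.10, reversed in the last. Of the values of named genes under the alternatives, 37 moved, 2 reversed and 1528 did not. All the moves and reversals came from averaging probe sets, where 215 values did not move. A gene with 1 probe set cannot move there, and another floor hardly changes a gene's own difference. The 1528 are therefore no measure of how stable the genes are. Of the list medians 122 moved, 4 reversed and 444 did not.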

Other observations

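MHC class I, antigen processing and interferon genes, a list made after Ly6c, Tap1 and Irf7 had been seen among the higher genes, had a median log2 difference of 0.53 at 0.1 h and 0.41 at 1.0 h against 0.0 h, each at percentile 99.96. At least 2-fold higher were 3 of 19 members at 0.1 h and 4 of 19 at 1.0 h. The antiviral gene Oas1a was 2.16-fold and 2.54-fold higher and the peptide transporter gene Tap1 2.61-fold and 3.26-fold higher. B2m, the light chain of MHC class I, had 36491, 20815 and 37350 on the 3 arrays. The list median for 1.0 h against 0.1 h was 0.23. Since the list was made from genes seen to be high, its percentiles are not independent evidence, and no alternative was run on it.

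RNA processing genes went both ways at 0.1 h. Rbm39, Srpk2 and Cpsf7 were 4.24-fold, 3.51-fold and 3.37-fold lower at 0.1 h than at 0.0 h, while Hnrnpf and Sfpq were 2.94-fold and 2.24-fold higher. The medians of this list, also made after the values were seen, were -0.03, 0.05 and -0.01 in the 3 comparisons, and those of the vacuolar ATPase list 0.20, -0.02 and -0.24. Atp6v0c was 1.86-fold lower at 1.0 h than at 0.0 h on its brightest probe set, and its other probe set was higher; the mean of both gave a log2 difference of -0.44.

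In the paragraphs that follow, the tests of scaling, of single probe sets, of leukocytes and of 3' bias were chosen only after the result was seen; that of gene length was chosen before. Immediate early and inflammatory genes were higher at 0.1 h and 1.0 h than at 0.0 h. Intensity-dependent scaling is argued against at 0.1 h, where the lowest median of both lists under quantile and cyclic loess normalisation was 0.39 against 2 bootstrap standard errors of 0.26. At 1.0 h it stays open, and the test could not decide. The medians under the main scaling, 0.29 for immediate early and 0.31 for inflammatory genes, were already under their bars of 0.36 and 0.46. Under quantile and cyclic loess normalisation the immediate early medians were 0.38 and 0.37 and the inflammatory medians both 0.32. The test of single probe sets came out on the side of their error by its rule, which counted any median inside the random range that way. The second-brightest probe sets of 12 genes of both lists had medians of 0.44 at 0.1 h and 0.07 at 1.0 h, at percentiles 92.52 and 61.9. Both medians lay inside the range of random lists, -0.12 to 0.53 and -0.27 to 0.29. Of the 12 genes, 9 were higher at 0.1 h and 8 at 1.0 h. They include Egr1 and Ccl2 but not Fos, Nr4a1, Ptgs2, Klf4, Cxcl2, Il6 or Irf7. The pattern was thus not borne out on these second probe sets. With so few genes, a median inside the random range does not tell error from a real difference. Error of single probe sets therefore stays open. More leukocytes in the later samples were read from 14 of 26 leukocyte markers, none of them in another fixed list. By its rule for both times together this test could not decide. At 1.0 h the leukocyte median was 0.33 and the inflammatory median 0.31, so more leukocytes could not be told apart from a response. The bright markers went apart: Spp1 had 18255 at 0.0 h and 6573 at 1.0 h, and Lgals3 12035 and 13664. At 0.1 h the leukocyte median was 0.02, at percentile 48.54 with a bootstrap standard error of 0.13, and the inflammatory median 0.52. For the 14 markers these values argue against more leukocytes at 0.1 h. Stronger 3' bias was not tested for the immediate early and inflammatory genes. The beta-actin 3' to 5' ratio was 10.4, 17.8 and 44.4 at 0.0 h, 0.1 h and 1.0 h, and that of GAPDH 15.3, 18.6 and 14.1. A response to the time course is untested, because each label had 1 array and both comparisons share the 0.0 h array.

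After median scaling, oxidative phosphorylation genes were higher on the 0.1 h array than on both others. Error of single probe sets is argued against by a percentile of at least 99.19 on second-brightest probe sets, and genes of short genomic length brighter on the 0.1 h array too: among random lists matched on level and genomic length the list was at percentile 100, with a random median of 0.08 against 0.56. The length of the transcripts was not matched, so brighter short transcripts stay untested. Intensity-dependent scaling is argued against for 0.1 h against 0.0 h, with a lowest median of 0.54 under quantile and cyclic loess normalisation against 2 bootstrap standard errors of 0.20, and stays open for 0.1 h against 1.0 h, with 0.21 and 0.27 against 0.24. Stronger 3' bias of the 0.1 h RNA stays open, since only 1 of the 2 control transcripts, GAPDH, had its highest 3' to 5' ratio there. A difference in the 0.1 h sample itself, from the time course or from handling, may be a candidate explanation and is untested.

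Second probe sets of the same gene followed the first only weakly. Probe sets with _g_at in their names were left out here, so the brightest is not always the one that gave a gene's fold above. The log2 differences of the brightest and the second-brightest of the others had a correlation across genes of 0.26, 0.16 and 0.12 in the 3 comparisons. These were over 394, 398 and 431 genes. Of genes at least 2-fold apart on the brightest of these probe sets, the second went the same way in 30 of 44, 14 of 22 and 27 of 42.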
